A study of Caenorhabditis elegans with 2 samples.

How the data were processed

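The data are ChIP-seq region lists from whole L3 larvae of Caenorhabditis elegans strain OP222, which expresses eGFP-DAF-12. The labels give 1 group of 2 samples and number them as biological replicates 1 and 2. Each sample was assigned to the group and its replicate number from its label.

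Per the deposited notes, the authors made each list from read alignments with a control alignment, once per replicate and once for both replicates pooled, in ce10 and in ce11. Peak caller, aligner, their versions and the IDR threshold were not given in the sources used here. The signal values were deposited by the authors as one number per region. Their scale is not stated, and they were used only to rank and describe regions and, between replicates, as log2 ratios across IDR peaks. The deposited −log10 q-value was not used for ranking because it reached a ceiling, 2.04 in the pooled ce11 list, which 55 regions shared. In each relaxed list the 30000 regions had nearly all the same width (344 bp for 29997 of those in the pooled ce11 list), as the lists hold background as well as peaks. The 150 IDR peaks in ce11 were the 150 regions with the highest signal in the pooled list, and the 138 in ce10 were likewise the highest of theirs. No read counts were in the lists, so depth is unknown and no counting error of the signal is given. Intervals on shares are exact (Clopper-Pearson) 95% intervals over peaks or genes. The p-values measure chance placement across peaks, not the spread between animals. The control alignments and signal tracks were not used here.

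Region positions fit within the chromosomes of WBcel235, the assembly that ce11 names, and its sequence, the Ensembl release 115 annotation and RefSeq gene symbols were used with the ce11 lists. The ce10 lists served only for their number of peaks and the overlap of replicates, for which random placement took the ce11 lengths. TSS were the 5' ends of annotated transcripts of 19973 protein-coding and 261 microRNA genes, without mature microRNA entries, and 612 tRNA genes were added for gene lists. Where a summit matched more than one annotation, it was put in the first that applied of the classes 5' UTR, coding exon, 3' UTR, intron, upstream to 2 kb and other intergenic. Symbols follow RefSeq, and names not found there were matched by the Ensembl name. Of the list members, 4 names were matched by neither (lep-5, ram-4, elt-5 and daf-21) and were left out. In an alternative added after the data were seen, daf-21 was counted as hsp-90.

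Tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The share of summits per chromosome was tested against the share of nuclear genome length by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 6 chromosomes. The share within 500 bp of a TSS was tested by 10000 random placements on the same chromosomes, one-sided, and annotation classes by the same number, two-sided, for which the smallest unadjusted p is 0.0002. Overlap of the 150 highest regions of each replicate counted summits within 100 bp, with 1000 random placements. For each of 25 gene lists, genes with a TSS within 2 kb of an IDR summit were compared with the other genes of the same biotypes by Fisher's exact test, two-sided, adjusted over the lists. For the lists of all microRNAs and all tRNA genes no other gene has the biotype, so the genes of the other biotypes served as background, a departure from the fixed design. For 10 motifs, presence on either strand within 50 bp of the summit was compared with a window 500 bp away, to the left for odd and to the right for even ranks, by an exact McNemar test, and the same test was run on 2080 hexamers. The fixed design had no test at the transgene loci; the number of regions there was compared later with that in windows of the same width.

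The genes named were those with a TSS within 2 kb of the 25 strongest peaks, every member with a peak of the heterochronic, heterochronic microRNA, dafachronic acid, dauer insulin and TGF-beta, and Wnt lists, up to 4 members of every other list, daf-12 and unc-119, and the known or proposed targets lit-1, myo-2, ceh-22, let-7, mir-84, mir-241, mir-48 and daf-9. Where several peaks lay within 2 kb of a gene, the highest-ranked was taken. Genes named for peaks with no TSS within 2 kb, and rps-3A and cept-2, were named after their values were seen.

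Alternatives were the 75 peaks with the highest signal, the 150 highest regions of either replicate alone, peaks within 50 kb of daf-12 and unc-119 left out, summits within 500 bp merged, other chance shares, TSS windows, overlaps, list lengths, motif windows and controls. Added after the data were seen were the 65 peaks in the 150 highest of both replicates, a GC-matched control taken from windows 300 to 1500 bp away, and 1000 random placements in place of Fisher's exact test. The scripts were tested on simulated data of the same size. With no effect, the X excess was called in 1.5% of 200 simulations, the TSS excess in 2.5% and AGTGCA in 0.50%, and with 20 simulations no hexamer passed. These simulated summits lay at random and independently of each other. The rates thus do not cover the higher GC content of the real summits than of their flanks, or the grouping of real summits. With the X share raised 1.8 times the call was made in 93.5%, with 20% of summits moved to a TSS in 98.5%, with 5 of 20 members of a list given a peak in 100% and with AGTGCA put into 12% of 150 windows in 72.5%. Of 60 shared peaks placed in a pair of lists, 60 were found. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.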

Results

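Binding of the nuclear hormone receptor DAF-12 to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) of an eGFP-DAF-12 fusion in whole Caenorhabditis elegans at the L3 larval stage. DAF-12 is the receptor of the steroid dafachronic acid and acts in dauer formation and developmental timing. The strain, OP222, carries the tagged gene as an integrated transgene in an unc-119 mutant background. The series holds 1 group of 2 samples, which the labels call biological replicates, with the sexes pooled. No control sample was analysed here. The files list regions with the authors' signal value for each, and no read counts, so the depth of each library is unknown. For each replicate and for the pooled replicates there was a relaxed list of 30000 regions. There was also a list of 150 peaks that passed the authors' threshold on the irreproducible discovery rate (IDR), a measure of how well ranks repeat between replicates. These 150 were the regions of highest signal in the pooled list, so a peak in it need not rank high in each replicate. All coordinates are 1-based positions in ce11.

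The first question was where DAF-12 was found. The strongest peaks lay upstream of a let-7 family microRNA gene, upstream of ribosomal protein genes, and in intergenic stretches of X without a nearby coding or microRNA gene. The peak of rank 3 had its summit at V:14366745, 462 bp upstream of mir-241, a developmental timing microRNA of the let-7 family, with a pooled signal of 135.7 (76.8 in replicate 1 and 59.3 in replicate 2). Upstream of rpl-3, the peak of rank 4 lay at III:3867568, 286 bp from the start of this gene for a large-subunit ribosomal protein, with a signal of 128.7 (69.3 and 61.2). On X, the peak of rank 1, at X:11094221, had a signal of 177.5 (76.9 and 102.1) and no coding or microRNA transcription start site (TSS) within 2 kb. Its nearest was that of W02H3.3 at 3965 bp, and a tRNA gene, W02H3.t1, started 1452 bp away. On III, the peak of rank 2, at III:12841572, had a signal of 153.9 (75.7 and 77.6), with the nearest TSS, that of Y37D8A.4, at 2609 bp.

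Of the 25 strongest peaks, 13 were on X and 10 had no coding or microRNA TSS within 2 kb, 7 of these on X. Their signals ranged from 73.7 to 177.5. On X, the peak of rank 5 lay 730 bp upstream of nspc-17 and near nspc-18, those of ranks 10, 11 and 14 lay 1063 to 1803 bp from F19H6.5, F20B6.9 and T27A8.7, that of rank 18 lay 94 bp upstream of F28C10.3, and that of rank 23 lay 443 bp upstream of epn-1, an epsin of the endocytic machinery. On autosomes, the peak of rank 6 lay 150 bp upstream of cdc-48.1, an AAA ATPase of protein degradation, with C06A1.6 and C06A1.7 also within 2 kb. That of rank 9 lay 581 bp from ZK1248.17 and 817 bp from H41C03.3, and that of rank 13 lay 415 bp upstream of rpl-35. Upstream of tag-340 and nhl-2 lay the peak of rank 15, and that of rank 19 upstream of Y17G9B.5, rpl-18A and cyc-2.1, a cytochrome c. The peak of rank 21 lay 23 bp from idhg-1, which encodes a subunit of isocitrate dehydrogenase, and 644 bp from mlcd-1. That of rank 24 lay 57 bp from tasp-1, with K01G5.10 and rnf-113 also within 2 kb. Of those without a coding or microRNA TSS within 2 kb, the peak of rank 7 (X:6296599) was in an intron of mom-1, that of rank 16 (X:2997063) in an intron of Y41G9A.17 and that of rank 20 (III:12612681) in an intron of Y111B2A.12. The peaks of ranks 8, 17, 22 and 25 on X, and that of rank 12 on V, were intergenic.

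The 2 replicates were compared as the only available measure of error. The strongest peaks recurred in both: all of the peaks of ranks 1 to 25 and 48 of those of ranks 1 to 50 were among the 150 highest regions of each replicate, including those at mir-241, rpl-3, cdc-48.1, nhl-2, lin-14, lin-42, din-1 and daf-12. Of the 50 lowest-ranked peaks, 0 were. The ranking itself nearly sets this: the pooled signal ran close to the replicates' signals added together, so a peak high in both could hardly rank so low. Among all IDR peaks, 65 were in the 150 highest of both replicates, 31 in those of replicate 1 only, 35 in those of replicate 2 only and 19 in neither. The lin-41 peak was strong in replicate 1 (signal 22.9, rank 85) and weak in replicate 2 (10.9, rank 4483). Counted directly, 63 of the 150 highest regions of replicate 1 (42%) had a summit within 100 bp of one of replicate 2, against a mean of 0.052 over 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). Across the 142 IDR peaks with a region in both replicates, the signals had a Spearman rho of 0.492 and a Pearson r of 0.526 on the log2 scale, a relation across regions, which are not independent replicates. The log2 ratio of replicate 1 to replicate 2 had an SD of 0.68 over these peaks, 0.37 over ranks 1 to 25 and 0.77 over ranks 76 to 150, and 19 peaks differed by more than 2-fold. By this SD, peaks of the lower ranks agreed less between replicates. Some had like signals in both, such as that of rank 148 (17.9 in each). Others rested mostly on 1 replicate, such as that of rank 146 (5.92 in replicate 1 and 27.9 in replicate 2).

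**Figure D1:**
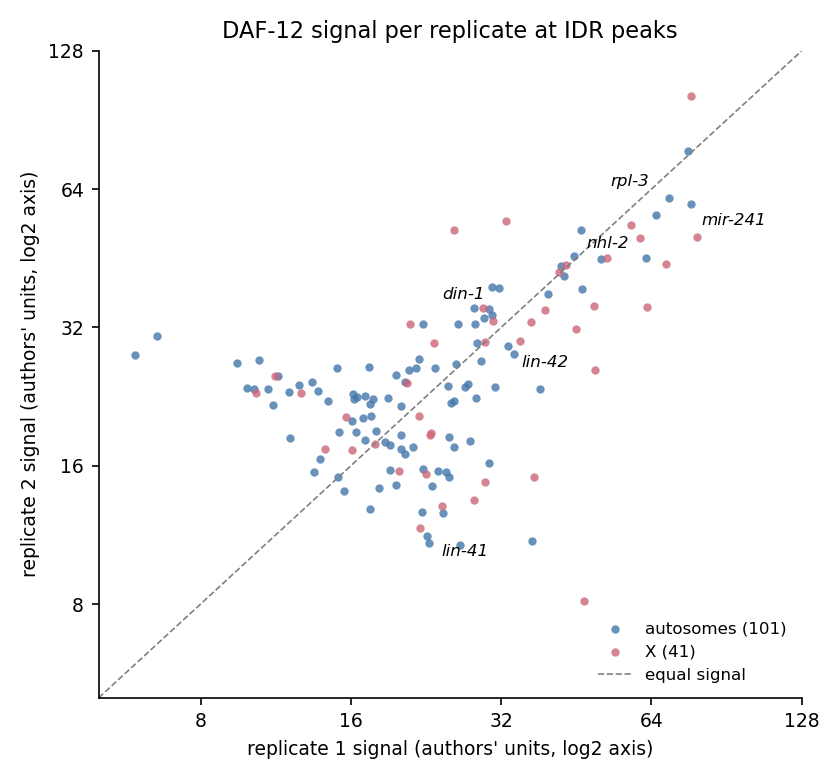
Signal in replicate 1 (x axis) against replicate 2 (y axis), in the authors' units on log2 axes, for the 142 IDR peaks with a region in both replicates; each point is a peak, coloured by chromosome, and the dashed line marks equal signal. The strongest peaks, such as those at mir-241 and rpl-3, lie near the line, and the points spread away from it at lower signal, as at lin-41.

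The second question was which genes lay near the peaks. A TSS within 2 kb of an IDR summit was found for 167 of 20234 protein-coding and microRNA genes. Heterochronic genes, which time larval cell fates, stood out: 6 of 19 had a peak (31.6%, exact 95% interval 12.6 to 56.6) against 0.796% of the other genes (odds ratio 57.5, Fisher's exact test, two-sided, adjusted p = 1.79e-07). They were mir-241, nhl-2 (a TRIM-NHL protein that acts with microRNAs, signal 89.4, 808 bp), lin-14 (a timing factor repressed by lin-4, signal 64.8), lin-42 (a Period homologue, signal 62.2), daf-12 itself (signal 60.4) and lin-41 (a TRIM-NHL protein repressed by let-7, signal 37.9). The peaks at lin-14 (X:11478946), lin-42 (II:1238126) and daf-12 (X:10637661) were in introns, 1157 to 1753 bp from an annotated start, and the lin-41 peak (I:9343994) was 1498 bp upstream. A weaker peak of rank 114 lay 151 bp from a lin-14 start at X:11465409, with a signal of 37.1 and no region of replicate 1 within 100 bp.

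Cytosolic ribosomal protein genes also stood out, with a peak at 7 of 84 (8.33%, exact 95% interval 3.42 to 16.42, against 0.784% of the other genes, odds ratio 11.5, Fisher's exact adjusted p = 7.08e-05). The 4 strongest were rpl-3, rpl-35 (signal 97.4), rpl-18A (86.2) and rpl-15 (70.5), and the summits of all 7 lay 22 to 415 bp from the annotated start. Members of the dafachronic acid pathway had a peak at 2 of 13 (Fisher's exact adjusted p = 0.0304), din-1, which encodes a corepressor of DAF-12, and daf-12. At din-1 peaks lay at II:11620167, 89 bp from a start, and at II:11619328 (signals 64.8 and 60). The call was lost in 5 of 11 other settings: with the peaks around the transgene's own genes left out (Fisher's exact adjusted p = 0.419), with windows of 500 bp (0.382), 1 kb (0.331) and 5 kb (0.0631), and under random placement (two-sided permutation adjusted p = 0.11). At 500 bp and 1 kb the odds ratios, 22.7 and 15.9, stayed near the 22.4 at 2 kb or somewhat below, while 1 member rather than 2 had a peak. The odds ratio fell further to 10.2 without the peaks around the transgene's own genes (1 member) and to 11.3 at 5 kb (2 members). Neuropeptide genes had a peak at 5 of 147 (3.40%, odds ratio 4.38, Fisher's exact adjusted p = 0.0359). The 4 strongest were ins-39 (signal 60), ins-13 (57.1), ins-17 (39.9) and ins-37 (38.9), which encode insulin-like peptides. The ins-39 peak had no region of replicate 1 within 100 bp, and ins-17 shared its peak with rps-3A, whose start was nearer. Chemoreceptor genes had fewer peaks than other genes, 1 of 1288 (0.0776% against 0.867%, odds ratio 0.0888, Fisher's exact adjusted p = 0.00459), at sri-5. The neuropeptide call was lost in 8 of 11 other settings and the chemoreceptor call in 6 of 11, among them with the peak set limited to those in the 150 highest of both replicates (Fisher's exact adjusted p = 1.0 and 0.374). Where Fisher's exact test lost the neuropeptide call, the odds ratio ran from 0 within 500 bp to 4.19 with the nearest TSS only. For chemoreceptors it ran from 0.139 to 0.207 in such settings, so their share stayed well below that of other genes.

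The other fixed lists did not pass with the IDR peaks and the 2 kb window. Stress response genes had a peak at 2 of 24 (Fisher's exact adjusted p = 0.0677), hsp-1 (signal 58.2) and hsp-60 (47.8), which encode chaperones. The chaperone gene hsp-90 also had a peak, of rank 58. Its summit was in an intron of hsp-90, 382 bp upstream of an annotated start of this gene, and the start of another gene was nearer, at 293 bp. In the fixed list hsp-90 stood as daf-21, a name the gene tables did not match, so it is not in this count. This omission decided the call: with hsp-90 counted, an alternative added after the data were seen, 3 of 25 stress response genes had a peak (12%, odds ratio 16.9, Fisher's exact adjusted p = 0.00672). The stress list also passed with the 75 strongest peaks (Fisher's exact adjusted p = 0.0291), replicate 2 alone (0.00738), a window of 5 kb (0.00329) and the peaks in the 150 highest of both replicates (0.0204). Heterochronic microRNAs had a peak at 1 of 9, mir-241 (Fisher's exact adjusted p = 0.470), and all microRNAs at 4 of 261, mir-241, mir-52 (signal 52.2), mir-2221 (33.7) and mir-1824 (33.6), with an adjusted p of 0.523. With a window of 5 kb, which takes in the peaks 2236 bp from mir-48 and 2363 bp from mir-84, 3 of 9 heterochronic microRNAs and 11 of all microRNAs had a peak (Fisher's exact adjusted p = 0.0173 for each), and all microRNAs also passed with replicate 1 alone (0.0259). Nuclear hormone receptors had a peak at 3 of 274 (daf-12, nhr-40 and nhr-19) and homeobox and GATA regulators at 1 of 84 (ceh-38). Genes for tRNAs had a peak at 4 of 612, W02H3.t1, ZK899.t1, C18A11.t2 and C18A11.t1, all on X, with an adjusted p of 1.0 for these 3 lists. In 14 lists, with 658 members in all, 0 members had a peak, and the lowest unadjusted Fisher's exact p among them was 0.409. These were dauer insulin and TGF-beta signalling (23 members), Wnt signalling (19), collagens (175), moulting and apical matrix (19), hypodermis and seam regulators (15), pharynx (17), body wall muscle (21), intestine (21), pan-neuronal (18), germline (24), cell cycle (20), fat metabolism (29), cytochrome P450, UGT and GST (185) and histones (72).

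The known or proposed DAF-12 targets were looked up one by one. The best region was taken in each replicate separately, so the 2 ranks given for a gene can belong to different regions. At mir-48 (V:14364412 to 14364509), a let-7 family microRNA beside mir-241, the nearest IDR summit was that of the mir-241 peak, 2236 bp away. The best region within 2 kb ranked 122 in replicate 1 (summit V:14364466) and 1254 in replicate 2 (summit V:14365579). At mir-84 (X:16022404 to 16022478) the IDR peak of rank 81 lay 2363 bp away, with signals of 20.7 and 24.2 in the replicates, and the best region within 2 kb ranked 927 and 493. At let-7 the best regions within 2 kb ranked 2030 and 2741, and at daf-9, which encodes the cytochrome P450 that makes dafachronic acid, 3845 and 13945. At lit-1, a kinase of Wnt signalling, they ranked 196 and 1250, at myo-2, a pharyngeal myosin, 14367 and 2367, and at ceh-22, a pharyngeal homeobox gene, 3865 and 474. Each of these 7 genes thus lacked an IDR peak within 2 kb. For mir-48 and mir-84 the nearest peaks, at 2236 and 2363 bp, lay just beyond this limit. Distances there are to the short annotated genes, and starts of any longer transcripts were not used.

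**Figure D2:**
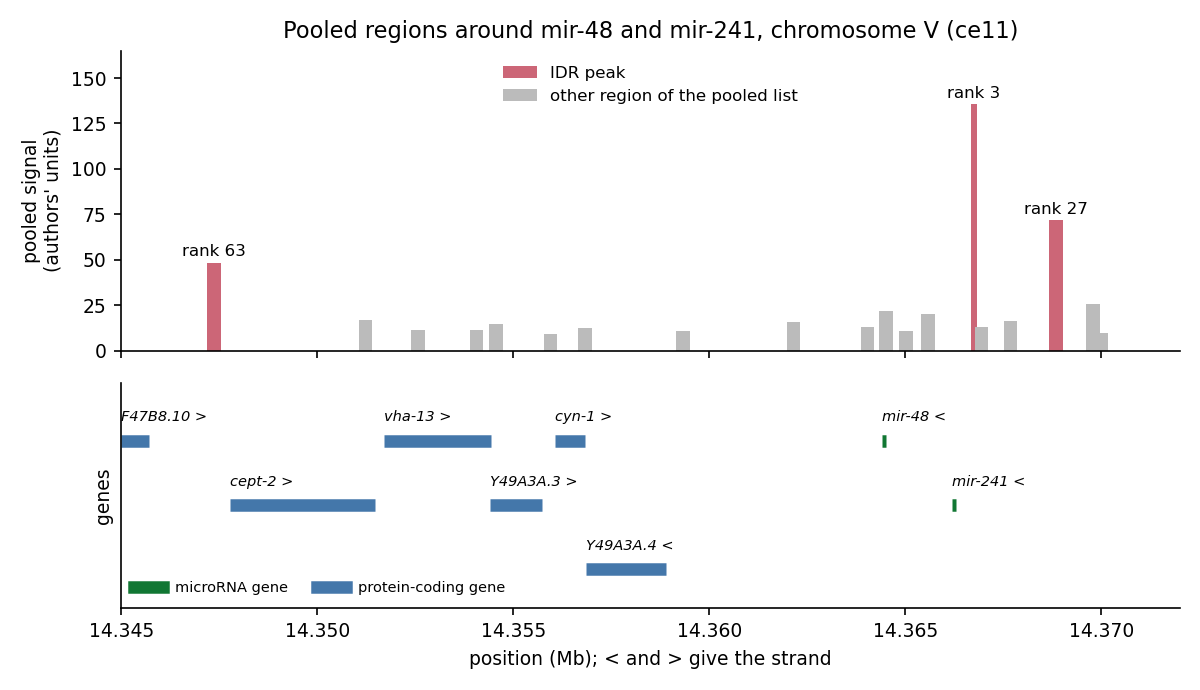
Regions of the pooled list around mir-48 and mir-241 on chromosome V, with position in Mb (x axis) and pooled signal in the authors' units (y axis) above the annotated genes; bars span each region, red for IDR peaks and grey for other regions. The peak of rank 3 is beside mir-241, that of rank 27 lies 2559 bp from its start, and that of rank 63 lies 396 bp from the start of cept-2.

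The third question was how the peaks were spread over chromosomes. Chromosome X held 43 of the 150 peaks (28.7%, exact 95% interval 21.6 to 36.6), against 17.7% of the genome length (exact binomial test, two-sided, p = 0.000836, adjusted over 6 chromosomes p = 0.00502). Chromosome III held 30 (20% against 13.7%, exact binomial adjusted p = 0.0966), and I, II, IV and V held 10.7%, 12.7%, 12.7% and 15.3%, each below its length share without passing the test. Regions in the lower-ranked part of the pooled list were on X more often than by length, at 19.8%, and against that share the X excess no longer passed (exact binomial adjusted p = 0.0602). The test treats peaks as independent, although some lay close together.

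**Figure D3:**
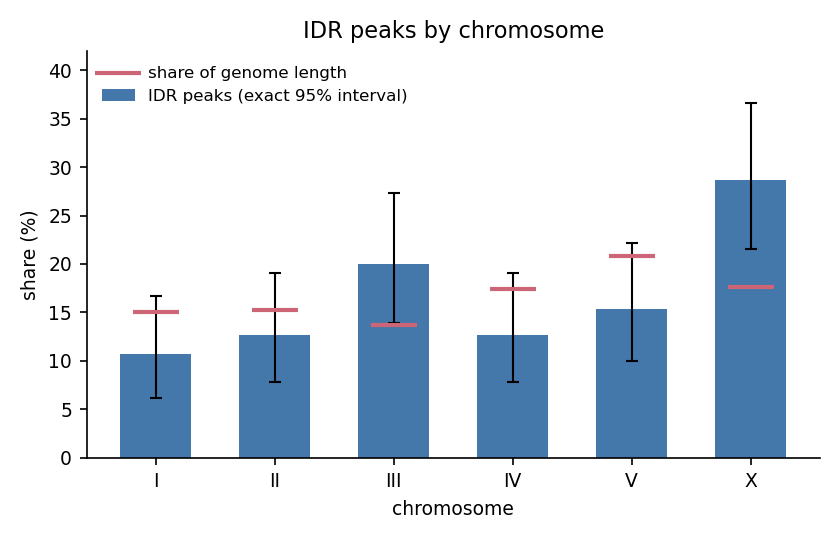
Share of the 150 IDR peaks on each chromosome (bars, in percent, with exact 95% intervals) and the share of genome length (red lines). The X bar stands at 28.7% with its interval above the length share of 17.7%, and the other intervals reach or nearly reach theirs.

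The fourth question was where the peaks lay relative to genes. Of the 150 summits, 59 (39.3%) lay within 500 bp of an annotated TSS, against 22.6% ± 3.46 (SD) over 10000 random placements on the same chromosomes (one-sided permutation p = 0.0001, the smallest these placements can give). The median distance was 818 bp, and 40 summits (26.7%) lay beyond 2 kb. Summits upstream of a gene by up to 2 kb made up 50.7% against 18.9% by chance, introns 20% against 33.4% and coding exons 1.33% against 23.7% (two-sided permutation, adjusted p = 0.0004 for each, the smallest these could reach together). Summits in 5' UTRs (4.0%), 3' UTRs (2.67%) and other intergenic sequence (21.3%) did not differ from chance (permutation, adjusted p = 0.152, 0.860 and 0.594). Fewer summits lay near a TSS on X than on autosomes: 9 of 43 X summits (20.9%, exact 95% interval 10 to 36) lay within 500 bp of a TSS, close to the 19.2% of random placement, and 50 of 107 autosomal summits did (46.7%, 37 to 56.6, against 24%), with a Fisher's exact p of 0.00333 for the difference in raw shares (odds ratio 0.302). Relative to random placement the excess was 1.09-fold on X and 1.95-fold on autosomes, and the 95% interval of their ratio, 0.302 to 1.04, included 1. This split of the chromosomes was chosen after the values were seen. Annotated starts of trans-spliced genes are only near the true start.

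**Figure D4:**
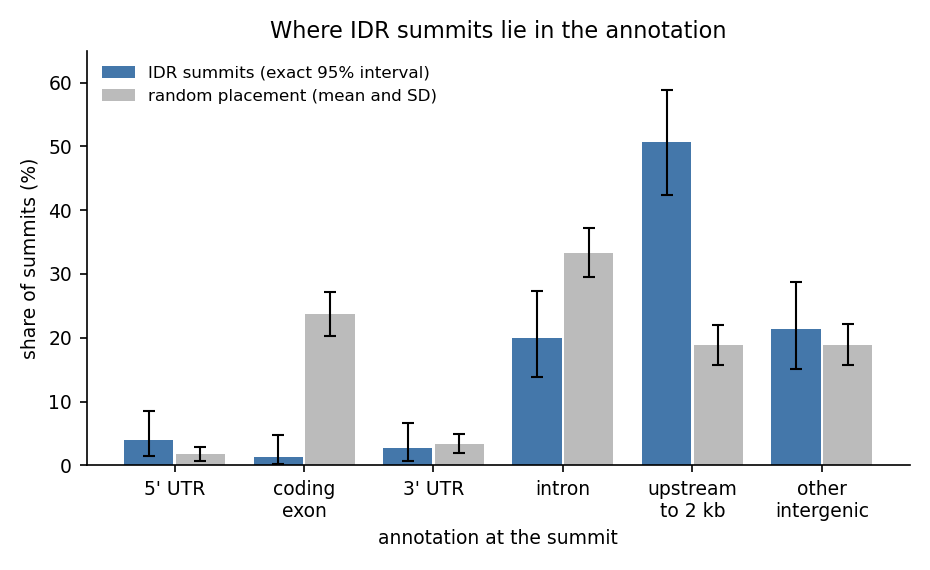
Share of the 150 IDR summits in each annotation class (blue bars, in percent, with exact 95% intervals) beside the share among random placements on the same chromosomes (grey bars, mean with SD). Upstream sequence stands at 50.7% against 18.9%, and coding exons at 1.33% against 23.7%.

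The fifth question was whether sequences known for DAF-12 and related receptors were found at the summits. Windows reaching 50 bp to either side of each summit were compared with windows 500 bp away. Of the 7 receptor hexamers listed beforehand, AGTGTG was present in 12.7% of summit windows and 1.33% of flanking windows (exact McNemar test, two-sided, adjusted p = 0.00111), and AGTGCA in 12.7% and 3.33% (adjusted p = 0.0220). AGTGCG (8.0% and 3.33%), AGTACA (10.7% and 4.67%), AGTTCA (2.67% and 4.0%), AGGTCA (3.33% and 1.33%) and AGGACA (4.0% and 2.67%) did not pass. The GA-repeat pentamer GAGAG was present in 46.7% and 21.3% (exact McNemar adjusted p = 0.000195). The GATA-type hexamer TTATCA (4.0% and 8.67%) did not pass, and TGAGTCA was in 0 windows of either kind. Summit windows were richer in GC than the flanks (46.8% against 37.9%). Against shuffled summit windows with the same dinucleotide counts neither AGTGTG (12.7% against 4.67%, exact McNemar adjusted p = 0.113) nor AGTGCA (12.7% against 10%, adjusted p = 0.925) passed, and over all 11 other settings AGTGTG passed in 8 and AGTGCA in 4. Against flanking windows matched for GC, a control chosen after the data were seen, these 2 hexamers did not pass either (AGTGTG 12.7% against 4.0%, exact McNemar adjusted p = 0.0640; AGTGCA 12.7% against 6.67%, adjusted p = 0.272), and GAGAG still did (46.7% against 19.3%, adjusted p = 1.04e-05).

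Among all possible hexamers, 29 passed against the flanks, 22 of them more frequent at summits. AGAGAC led, in 24.7% of summit windows and 2.67% of flanks (exact McNemar adjusted p = 7.25e-05), followed by GAGAGA (32.7% and 7.33%) and AGAGAG (26% and 5.33%), while TAAAAA was less frequent at summits (8.67% and 32%). AGTGTG took place 20 and AGTGCA place 74. With flanks matched for GC, 15 hexamers passed, 14 of them more frequent at summits, led by GAGAGA (32.7% and 8.67%) and CGCGCA (16.7% and 1.33%).

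**Figure D5:**
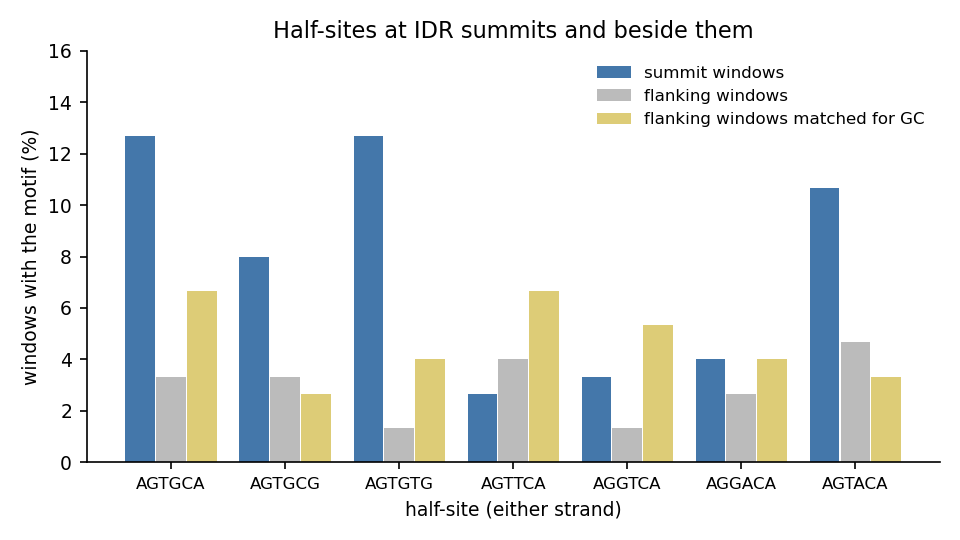
Share of the 150 windows holding each receptor hexamer on either strand (y axis, in percent) at IDR summits (blue), in windows 500 bp away (grey) and in nearby windows matched for GC (yellow); bars are shares of windows and carry no replicate error. AGTGCA and AGTGTG each stand at 12.7% at summits, and their share beside the summits is higher in the GC-matched windows.

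The last question was what the lists show at the genes that the strain carries in extra copies. At daf-12 (X:10635908 to 10666875) and 50 kb to either side there were 2 IDR peaks, of ranks 40 (signal 60.4, with 29.7 in each replicate) and 126 (X:10640654, signal 36.1), both in introns of daf-12. The pooled list held 65 regions in that stretch, replicate 1 held 77 and replicate 2 held 74. At unc-119 (III:10902641 to 10908935) there were 0 IDR peaks in the same margin and 26 pooled regions, the highest at rank 2399. Reads from the transgene and from the native genes cannot be told apart in these lists.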

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

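The alternatives with both replicates' 150 highest regions, GC-matched controls and random placement for lists were chosen after the data were seen. With the authors' peaks reduced to the 75 of highest signal, 1 receptor hexamer passed, where 2 had with all 150. The hexamer that was lost, AGTGCA, was in 14.7% of those summit windows and 2.67% of their flanks, so its contrast did not shrink while fewer windows were tested. With the ce10 list there were 138 peaks. The share of peaks on X was 27.7% to 36.9% over 8 alternatives and kept its direction in each. It missed the threshold against the lower-ranked part of the pooled list (28.7%, exact binomial adjusted p = 0.0602), whose own X share of 19.8% exceeds the length share of 17.7%. With 1 replicate's regions it was 32% to 34%. The share of summits within 500 bp of a TSS passed in all 10 alternatives (22.7% within 250 bp, 56% within 1 kb), with 34.7% to 38.7% for 1 replicate's regions. Sharing between replicates passed in all 8, from 16% with lists 5 times as long to 64% with lists of 75. The highest region at daf-12 ranked 43 to 45 in single replicates against 40 in the pooled list.

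Of 25 gene lists, 5 passed, and 6 with daf-21 counted as hsp-90, which was added after the data were seen. The count fell to 2 with a TSS window of 500 bp, 2 with 1 kb, 3 with the nearest TSS only and 2 with random placement, was 4 with the 75 strongest peaks, 4 without the transgene loci, 4 with the 65 peaks in the 150 highest of both replicates and 6 with 5 kb, and was 5 to 6 with 1 replicate's regions. At 5 kb heterochronic microRNAs, stress response genes and microRNAs were gained. Heterochronic and ribosomal protein genes passed in all 11 alternatives, the dafachronic acid list in 6, chemoreceptors in 5 and neuropeptides in 3. Within 500 bp, 0 neuropeptide genes had a peak, which lost the call. No direction can be read from that count, since few genes of any kind had a peak so near. Under random placement, which accounts for genes with many starts, the heterochronic and ribosomal lists each had an adjusted p of 0.025, the smallest these could reach together. Over the single gene lists and motifs, 345 alternatives gave the same call, 30 lost it and 10 gained it. In 1 more, neuropeptides within 500 bp, the call was lost with a count of 0. Most of the 345 came from lists and motifs that had not passed, among them the lists without any member at a peak. The total thus says little on how stable the passing calls were. The gains were stress response genes in 5 alternatives, microRNAs in 2, heterochronic microRNAs in 1, and AGTGCG and AGTACA in 1 each. The cause of the other changes was not tested.

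Of 7 receptor hexamers, 2 passed. The count was 1 with a window of 25 bp to either side, 1 with controls 1000 bp away, 0 with shuffled windows that keep dinucleotide counts, 0 with GC-matched controls and 0 with the 65 peaks in the 150 highest of both replicates, and 1 to 4 with 1 replicate's regions (4 with those of replicate 2, AGTGCG and AGTACA among them). The shuffled and GC-matched controls have the GC content of the summits or nearly so (45.8% against 46.8%). With the 65 peaks the shares were much as with all 150 (AGTGTG 13.8% against 1.54%, AGTGCA 13.8% against 3.08%), and fewer windows were tested. AGTGTG passed in 8 of 11 alternatives, GAGAG in 9 and AGTGCA in 4. A stricter IDR threshold, the X share in ce10 and the transgene loci in ce10 were not run, since the lists used here carry no IDR value and the ce10 lengths and gene positions were not used here. Depth was unknown, so weak signal at genes such as let-7 cannot be told from limited depth.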

Other observations

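The tests on grouping of summits, on GACGCA, on longer sequences, of the 75 strongest peaks against the lower-ranked regions and of X summits near a TSS were chosen after the results were seen. So were the region densities within 5 kb and at unc-119. The X shares of the IDR peaks without the transgene loci, and of all 150 against the lower-ranked regions and against protein-coding genes, had been chosen in advance as alternatives. Their use to weigh explanations of the X pattern was set after the results were seen. IDR peaks lay in groups at a few loci. Around F45D3.1 and F45D3.2 on V, 6 peaks lay between V:12528396 and V:12540147, 5 of them in intergenic sequence that is not within 2 kb upstream of a gene, the strongest with a signal of 98.2 (rank 12). At lin-14, 3 peaks lay between X:11465409 and X:11482362, with ranks 114, 32 and 57. From cept-2 to mir-241, 3 peaks lay between V:14347370 and V:14368842, with ranks 63, 3 and 27. In all, 32 pairs of summits lay more than 500 bp and up to 20 kb apart, against a mean of 4.84 and a highest value of 16 over 10000 random placements (one-sided permutation p = 0.0001, the smallest these can give), a count made after the groups were seen. Preference for sequence near a TSS is argued against as the whole source, since summits put at their own distance and side from random TSS gave a mean of 5.45 pairs and at most 17 (permutation p = 0.0001). An uneven spread like that of the lower-ranked regions is argued against too, since draws from these gave a mean of 4.96 and at most 16 (permutation p = 0.0001). Regions ranked between the IDR peaks and that lower-ranked part were not drawn, so their spread was not tested. The 6 peaks around F45D3.1 and F45D3.2 all lay more than 500 bp and less than 20 kb from each other. Every pair among them is thus in the 32, and this locus supplied a large part of the count. The placements were not repeated without it, so they do not tell grouping at many loci from grouping at a few. Mappability, open chromatin and copy number at the grouped loci were not tested.

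The leading hexamers overlap in longer sequences. GAGACGCAG was in 14 summit windows (9.33%) and 0 flanking windows, and GAGAGAGA in 12 (8.0%) and 0. GACGCA was in 27.1% of the 59 summit windows within 500 bp of a TSS and in 8.79% of the other 91 (Fisher's exact adjusted p = 0.0424 over 8 such comparisons), and the other 7 comparisons, by TSS or by X, did not pass.

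The X pattern was that summits were on X more often than by length and there less often near a TSS. Extra copies of the tagged clone as the whole source are argued against by the X share with the transgene loci left out (27.7%, exact binomial adjusted p = 0.0144). A general excess of listed regions on X stays open: of the 75 strongest peaks 36% were on X against 19.8% of the lower-ranked regions (exact binomial adjusted p = 0.00708), but all 150 peaks missed the threshold in that comparison (exact binomial adjusted p = 0.0602). A lower density of TSS on X would give fewer summits there, not more. X holds 13.7% of protein-coding genes, which is below its length share. Passing against that lower share (exact binomial adjusted p = 1.16e-05) thus followed from the length test and decides nothing further. For the smaller share of X summits near a TSS, a lower density of TSS stays open. The excess near a TSS was 1.09-fold on X and 1.95-fold on autosomes. Their ratio was 0.559, with a 95% interval from 0.302 to 1.04 that includes equal excess. Mappability, open chromatin and the control's coverage of X were not tested, and no biological explanation was tested, since the design has 1 group.

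The promoter pattern was that summits lay near a TSS, ribosomal protein genes among them. Strong ChIP signal at active promoters without the receptor's own sequence is a candidate explanation, which would leave fewer promoter summits with AGTGCA or AGTGTG. These were in 23.7% of summit windows within 500 bp of a TSS and 20.9% of the others (Fisher's exact p = 0.691). This met the criterion set beforehand against the explanation, a share near a TSS equal to or above that of the others. The difference of 2.85 points had a 95% interval from −10.2 to 17 points, however, too wide to decide. Neither hexamer passed against shuffled or GC-matched windows, so their presence need not mark the receptor's own sequence. Different leading sequences at promoters and elsewhere stay open too. AGAGAC was in 22% and 26.4% (Fisher's exact p = 0.568), which met the criterion set beforehand against a difference, a p of 0.05 or more with shares within 5 points. The 95% interval of the difference, from −17.5 to 10.1 points, reaches well beyond 5 points, so the criterion was met by less than the spread, and GACGCA was more frequent near a TSS, as given above. No biological explanation was tested.

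The daf-12 pattern was that listed regions were dense around the gene. The 65 pooled regions within 50 kb exceeded the number in 98.7% of windows of that width on X (median 47), and the 36 regions within 5 kb of the gene exceeded 99.9% (median 15). This is consistent with extra copies of the tagged clone that raise the background there, and it could also come from binding of DAF-12 at its own gene. At unc-119, which the strain also carries in the transgene, 26 regions within 50 kb exceeded 23.5% of windows on III and 5 within 5 kb exceeded 48.3%, so no such density was seen there. The extent of each gene's copy in the transgene was not used here, and no biological explanation was tested.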
